A study of Mus musculus with 6 samples.

How the data were processed

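Gene expression was measured by RNA sequencing in 6 libraries of sorted bone marrow cells from C57BL/6J mice, with 2 libraries in each of 3 populations. Groups were taken from the labels, which call the libraries of a population biological duplicates. BaP (named in the labels as a basophil precursor) was gated as lineage-negative, CD34-positive, c-Kit-negative and MAR1-positive. MAR1HI and MAR1INT were both gated as lineage-negative, CD34-negative, c-Kit-negative and CD200R3-positive, and were parted by a high or an intermediate MAR1 level. MAR1 is a monoclonal antibody to the alpha chain of the high-affinity IgE receptor. Per the labels, total RNA was extracted with TRIzol LS and libraries came from a kit that enriches RNA sequences by capture. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2 to the mouse genome build mm10 and summarised with StringTie. The notes used here name no versions, and the options and the annotation release were not stated.

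The deposited tables hold, per the file headers, 3 values for each gene: coverage (a signal, the mean read depth per base of the gene's transcripts), FPKM and TPM. The authors' TPM column summed to 1000000 in every library, and the ratio of the authors' FPKM to their coverage had 1 lowest value per library, shared by most well-covered genes, which gave the number of aligned bases behind each table. No read counts were used here, so no counting interval could be given, and precision was judged from the spread between the 2 libraries of a group. The implied aligned bases per library lay between 4.75 and 5.28 gigabases. Gene IDs were joined to symbols with a reference gene table of GRCm38.p6: 24462 of 24532 IDs matched and 70 did not. As a check of the build, 24247 of the 24462 matched genes (99.1%) overlapped their reference interval on the same chromosome. Coordinates are given as in the files (mm10, counted from 1). Values of gene IDs listed in several parts were summed. No mitochondrial genes were listed, so the list of mitochondrially encoded genes was not tested.

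The test, the filter, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is said to have been made afterwards. Genes with a TPM of 1 or more in at least 2 of the 6 libraries were tested (11337 genes). Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 1 term per group over all 6 libraries, which left 3 residual degrees of freedom and a median of 6.39 prior degrees of freedom. Log2 changes on this scale understate the change of genes at a low level. The contrasts were MAR1HI minus BaP, MAR1INT minus MAR1HI and MAR1INT minus BaP, each two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. A moderated F test over the 3 groups used the same adjustment. An exact permutation test of 2 libraries against 2 cannot give a p under 0.333, so the gene tests rest on limma's pooled estimate of the spread. Genes highest or lowest in MAR1HI had to be called in both contrasts that hold MAR1HI, in opposite directions. The position of MAR1HI between the other groups was a median over genes called in MAR1INT minus BaP. For each gene the MAR1HI minus BaP difference was divided by the MAR1INT minus BaP difference (0 at BaP, 1 at MAR1INT). The range over the 8 choices of 1 library per group is given with it. These choices reuse the same libraries and genes, so the range is not a full measure of the error. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.

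Gene lists were tested with limma's camera on the same values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 87 tests of 29 lists in 3 contrasts (lists with fewer than 5 tested members were not tested). Repeats used a correlation estimated from these libraries and fry, a rotation test that asks whether the genes of a list move one way on balance and does not compare them with other genes. Members were counted as higher, lower or not past the threshold, over all genes tested and adjusted over the list alone. The lists were basophil granule and effector genes, basophil surface receptors, mast cell genes, hematopoietic stem and progenitor genes, lineage transcription factors, S phase genes, G2 and mitosis genes, cell cycle inhibitors, ribosome biogenesis, oxidative phosphorylation, glycolysis, eicosanoid synthesis, cytokines and chemokines, immediate early genes, interferon-stimulated genes, adhesion and migration, granule and exocytosis machinery, Fc epsilon receptor signalling, JAK-STAT5 response, apoptosis regulators, heat shock and dissociation, and markers of dendritic cells, B and plasma cells, T and NK cells, neutrophils, monocytes and macrophages, eosinophils, erythroid cells, and megakaryocytes and platelets. Some genes stand in several lists, such as Kit, Cpa3, Myb and Ccr3. The sort markers were kept in their lists, so their calls are not independent of the gates.

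Named genes followed a fixed rule. For each contrast these were the 12 called genes with the largest rise and the 12 with the largest fall, among genes with a mean TPM of 5 or more in the higher group whose 2 values in one group both lay above the 2 values in the other. Predicted genes, microRNA and small nucleolar RNA genes, pseudogenes and immunoglobulin or T cell receptor segments were left out. The 4 members of a list with the largest absolute change, up to 8 of the genes highest or lowest in MAR1HI and the sort markers Cd34, Kit, Fcer1a and Cd200r3 were named too.

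The procedure was tested on simulated data with the spread of these libraries and 200 changed genes among 11337 in each of 5 simulations per contrast. Changed genes were drawn only from those with a mean level above about 20 TPM. The recovered shares therefore do not cover genes at lower levels, and the shares of false calls hold for 200 changed genes. It recovered 22.4% of genes changed 2-fold, 94.9% of those changed 4-fold and 99.4% of those changed 8-fold for MAR1HI minus BaP, with 1.9% false calls. For MAR1INT minus MAR1HI these were 29.6%, 93.1% and 99.7%, with 10% false calls. For MAR1INT minus BaP they were 24.8%, 90.4% and 99.7%, with 7.7% false calls, so the share of false calls exceeded the nominal rate in both contrasts with MAR1INT, whose libraries had the widest spread. All 15 of 15 simulated lists of 20 changed genes were found, and 0 unchanged lists had p under 0.05. Genes were simulated independently of each other, so this does not test the list calls where genes are correlated. In the real lists the estimated correlation reached 0.686 (immediate early genes).

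The alternatives were a pseudocount of 0.1, no filter on low values, a mean TPM of 5 or more, FPKM in place of TPM, quantile normalization, median-of-ratios scaling, robust eBayes, array weights, a replicate block, only the 2 groups compared, an absolute log2 change of 1 or more, an adjusted p under 0.01, the highest row kept per symbol, and leaving out each of the 6 libraries in turn. Where this left a group with 1 library, limma's pooled spread was used, so that the lone library was assumed to vary like the other groups. A repeat without genes listed at 0 in a whole group, and counts of called list members without each library, were added after seeing the data.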

Results

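The series profiled gene expression in basophil progenitors and related cells sorted from mouse bone marrow. The 6 libraries fell into 3 groups of 2 biological duplicates: BaP, a CD34-positive precursor population that binds MAR1, an antibody to the IgE receptor, and a pair of CD34-negative, CD200R3-positive populations with a high (MAR1HI) or an intermediate (MAR1INT) level of MAR1 binding. The comparisons ask how the transcriptome of the CD34-positive precursors differs from that of the CD34-negative populations, and where MAR1HI stands between the others. Values are TPM, given for a group as mean ± SD over its libraries (SD, n = 2), and differences are log2 changes of TPM + 1 with limma's adjusted p.

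The tables implied 4.90 and 4.83 gigabases of aligned sequence in the BaP libraries (replicates 1 and 2), 5.10 and 5.28 in MAR1HI, and 4.82 and 4.75 in MAR1INT. At that similar depth, 10983 and 11544 genes reached a TPM of 1 in BaP, 10710 and 11038 in MAR1HI, and 9604 and 9705 in MAR1INT. The SD between the duplicates over the tested genes was 0.42 (log2) in BaP, 0.43 in MAR1HI and 0.67 in MAR1INT. The correlation across genes between duplicates (genes are not independent replicates) was 0.960, 0.977 and 0.927. Histone genes took 15.2% and 17.6% of TPM in BaP, 18.6% and 12.03% in MAR1HI, and 8.23% and 7.83% in MAR1INT.

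Transcripts of the genes used for sorting differed among the groups. Cd34 (gene 12490, mm10 chromosome 1, 194938821 to 194961292) stood at 48.3 ± 6.00 TPM (SD, n = 2) in BaP, 6.15 ± 2.09 in MAR1HI and 0.0669 ± 0.0946 in MAR1INT. It fell in every contrast (MAR1HI minus BaP -2.81, adjusted p = 0.0122). Kit (gene 16590, chromosome 5, 75574987 to 75656721), the stem cell factor receptor, stood at 41.7 ± 4.44, 3.65 ± 1.01 and 0.247 ± 0.286 TPM, although all 3 gates excluded c-Kit protein. It fell between BaP and MAR1HI (log2 change -3.21, adjusted p = 0.00753) and again in MAR1INT (-1.90, 0.0172). Cd200r3 (gene 74603, chromosome 16, 44943678 to 44981380) rose from 833 ± 17.1 to 1589 ± 18.3 (0.93, adjusted p = 0.0281) and to 2519 ± 250.2 TPM (0.66, adjusted p = 0.0285). Fcer1a (gene 14125, chromosome 1, 173221271 to 173227229), which encodes the protein that MAR1 binds, stood at 834 ± 81.9, 1329 ± 166 and 478 ± 78.8 TPM. It was lower in MAR1INT than in MAR1HI, with a log2 change of -1.48 (adjusted p = 0.00155), the order of the MAR1 gates. Its difference between MAR1HI and BaP was not called (0.67, adjusted p = 0.126).

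**Figure D1:**
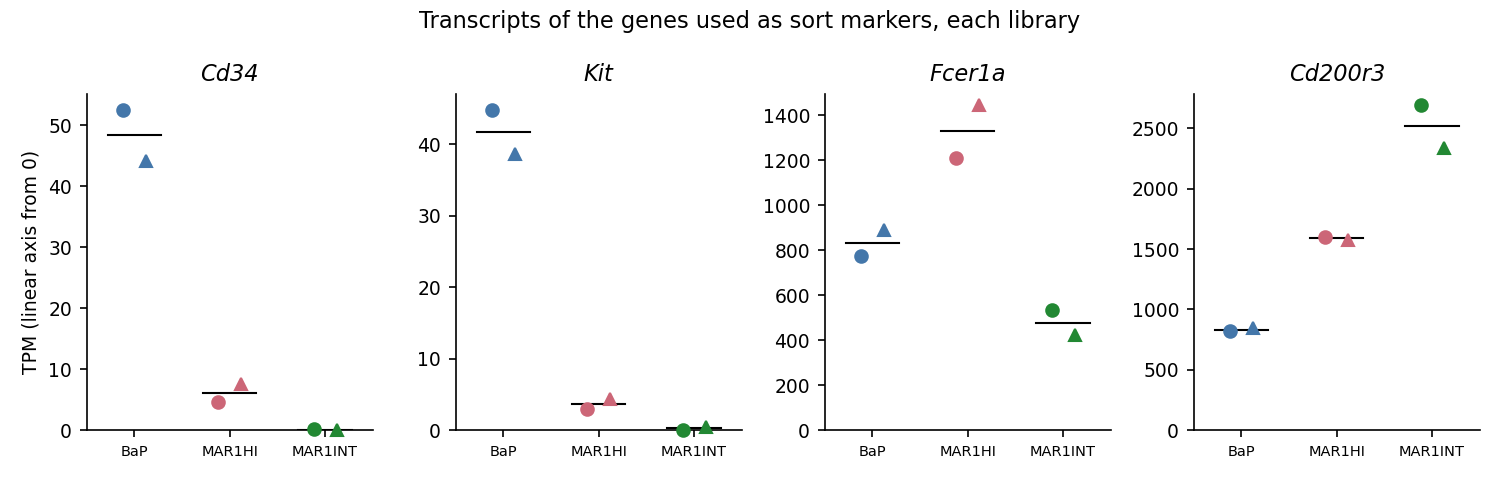
TPM (linear axes from 0) of Cd34, Kit, Fcer1a and Cd200r3 in each of the 6 libraries, for 3 groups. Circles mark replicate 1, triangles replicate 2 and lines the mean of each group. Cd34 and Kit were highest in both BaP libraries, Fcer1a in both MAR1HI libraries and Cd200r3 in both MAR1INT libraries.

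With the spread pooled over the 3 groups, most called differences separated MAR1INT from the others. This was less so with only the 2 groups compared. In those fits 1062 genes were called between MAR1HI and BaP, 1316 between MAR1INT and MAR1HI and 3204 between MAR1INT and BaP. Of 11337 genes tested, 3012 differed among the 3 groups (F test). Between MAR1HI and BaP 207 genes rose and 75 fell, between MAR1INT and MAR1HI 260 rose and 1640 fell, and between MAR1INT and BaP 1263 rose and 2311 fell. At an unadjusted p under 0.05 the 3 contrasts held 1980, 3495 and 4861 genes. The share of called genes that rose was 73.4%, 13.7% and 35.3%, and it depended on the scaling. With FPKM it was 59.0%, 17.0% and 28.7%, with quantile normalization 56.9%, 45.3% and 55.1%, and with median-of-ratios scaling 60%, 39.7% and 41.4%. The median tested gene changed by 0.24, -0.36 and -0.16 (log2) in TPM and by 0.04, -0.33 and -0.32 in FPKM. It changed by 0.02, 0.11 and 0.11 after quantile normalization, and by -0.04, -0.11 and -0.17 with median-of-ratios factors. Of 87 list tests 48 passed with the preset correlation, 25 with fry and 0 with an estimated correlation (adjusted p from 0.288 to 0.983).

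**Figure D2:**
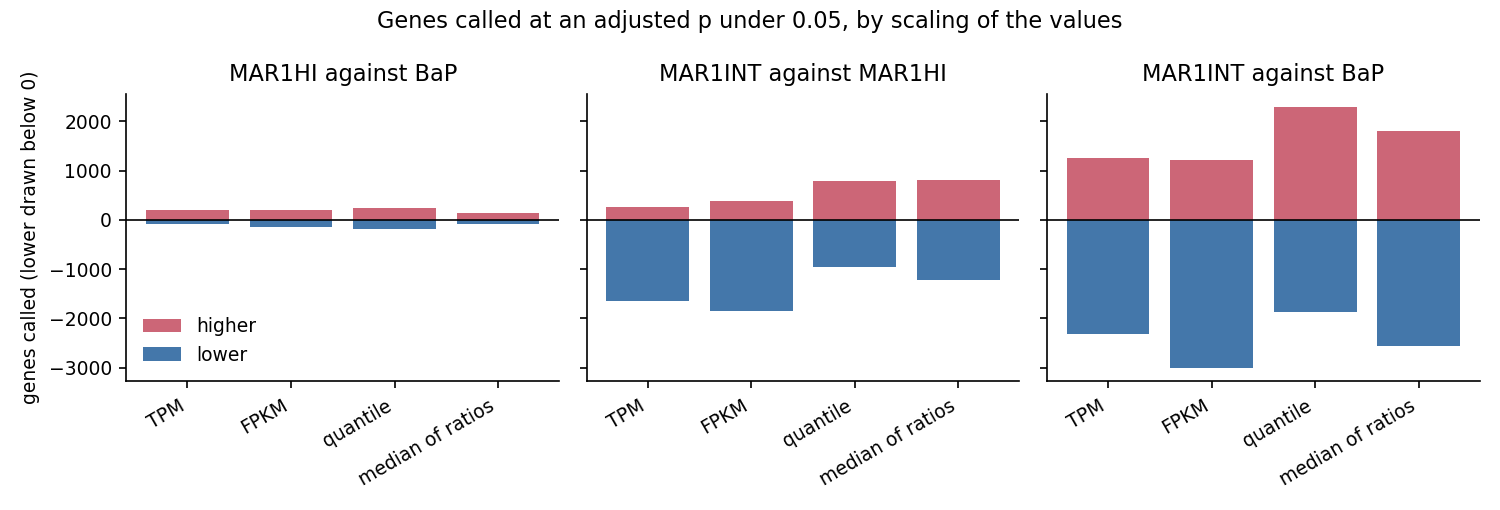
Number of genes called at an adjusted p under 0.05 (vertical axis, genes that fell drawn below 0) in the 3 contrasts, for TPM as analysed and for the 3 other scalings. In MAR1INT against MAR1HI 260 genes rose and 1640 fell in TPM, against 786 and 948 after quantile normalization. In MAR1INT against BaP more genes rose (2302) than fell (1877) only after quantile normalization.

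The first comparison set the CD34-negative MAR1HI cells against the CD34-positive BaP. Of basophil surface receptors 12 of 27 rose in MAR1HI, of cytokines and chemokines 7 of 12 and of adhesion and migration genes 10 of 21. Like all others, these lists lost their calls with an estimated correlation. Some genes of eosinophil granules, MHC class II presentation and macrophages fell, as did the progenitor genes Cd34 and Kit. No tested member of either cell cycle list was called. Among the genes that rose most were the chemokines Ccl6, from 48.9 ± 0.772 to 363 ± 18.1 TPM (2.87, adjusted p = 0.000187), and Ccl4, from 31.6 ± 21.5 to 242 ± 75.4 (3.04, 0.00856). The receptor subunit Il7r rose from 3.55 ± 2.21 to 61.5 ± 20.8 TPM (3.83, 0.00313) and the immune surface protein Cd7 from 2.69 ± 1.77 to 84.0 ± 29.4 (4.57, 0.000871). The beta-defensin gene Defb40 was listed at 0 in both BaP libraries and at 20.3 and 29.4 TPM in MAR1HI. The complement receptor C3ar1 rose from 7.18 ± 1.35 to 68.1 ± 35.6 TPM and the serotonin transporter Slc6a4 from 1.63 ± 1.68 to 19.8 ± 1.61. The G protein-coupled receptor Gpr174 rose from 0.459 ± 0.566 to 27.3 ± 5.76 TPM and the adaptor Skap1 from 7.07 ± 3.93 to 70.5 ± 8.50. Evi2b (3.19), which shares its position with other genes and is uncertain in level, the adhesion molecule L1cam (2.86) and the mucin Muc20 (2.84) completed the 12 largest rises.

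The largest falls between BaP and MAR1HI held genes of other granulocytes and antigen-presenting cells. Epx, the peroxidase of eosinophil granules, fell from 49.1 ± 22.4 to 0.295 ± 0.0263 TPM (-5.20, adjusted p = 0.000937). Prg3, a granule protein, fell from 64.7 ± 44.5 to 0.816 ± 1.15 (-5.15, 0.00535) and the ribonuclease gene Ear1 from 173 ± 122 to 0.596 ± 0.842 (-6.67, 0.0123). Ear6, a similar ribonuclease gene, stood at 40.7 and 9.52 TPM in BaP and was listed at 0 in both MAR1HI libraries. The MHC class II genes H2-Eb1 (-4.41, 0.0361) and H2-Aa (-4.01, 0.00822) and their chaperone Cd74 (-4.07, 0.0105) fell as well, Cd74 from 235 ± 167 to 11.3 ± 2.94 TPM. The lectin gene Clec4b1 stood at 46.9 and 32.9 TPM in BaP and was listed at 0 in MAR1HI. Bcl2a1d (-4.06) and Bcl2a1a (-3.94), near-identical copies of an anti-apoptotic gene whose separate levels are uncertain, were called lower too. The largest values belonged to the histone gene H4bc24 (-8.26, adjusted p = 0.0146), which has many near-identical copies, and to the small RNA Scarna13. This RNA overlaps the microRNA gene Mir3069 and was listed at 0 in MAR1HI after 239.9 and 208 TPM in BaP.

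Of basophil surface receptors 12 of 27 tested members rose and 0 fell (adjusted over the list alone, 19 and 1). The list passed its test (list adjusted p = 5.10e-09, and adjusted p = 0.438 with an estimated correlation). The interleukin 18 receptor Il18r1 rose from 43.0 ± 10.9 to 233 ± 20.9 TPM. The integrin Itga2 rose from 24.5 ± 4.92 to 127 ± 44.1 and the histamine receptor Hrh4 from 52.9 ± 1.44 to 231 ± 18.5. Of cytokines and chemokines, 7 of 12 tested members rose and 0 fell (adjusted over the list alone, 8 and 1, list adjusted p = 6.97e-06, and adjusted p = 0.508 with an estimated correlation). They held Ccl3, from 178 ± 47.9 to 1014 ± 153 TPM, and the type 2 cytokine Il4, from 36.6 ± 6.51 to 150.2 ± 30.8. In adhesion and migration 10 of 21 rose and 1 fell (adjusted over the list alone, 16 and 1, list adjusted p = 5.59e-09, and adjusted p = 0.524 with an estimated correlation). The chemokine receptors Ccr3 (5.46 ± 0.215 to 33.7 ± 7.87 TPM), Ccr2 (70.7 ± 20.5 to 252 ± 30.6) and Cxcr2 (47.5 ± 12.3 to 165 ± 45.9) were among them. Without BaP replicate 1, BaP replicate 2, either MAR1HI library and either MAR1INT library, the receptors that rose numbered 5, 9, 0 and 15, the cytokines and chemokines 5, 6, 1 and 8, and the adhesion genes 3, 6, 0 and 15.

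Among basophil granule and effector genes, 6 of 17 tested members rose and 0 fell (adjusted over the list alone, 8 and 0, list adjusted p = 0.00078, and adjusted p = 0.508 with an estimated correlation). Alox15, a lipoxygenase, rose from 134 ± 16.9 to 441 ± 101 TPM. Without either BaP library 4 rose, and without either MAR1HI library 0. In Fc epsilon receptor signalling 3 of 25 rose and 0 fell (adjusted over the list alone, 7 and 0, list adjusted p = 8.57e-05, and adjusted p = 0.618 with an estimated correlation). The kinases Btk (1.26, adjusted p = 0.0486) and Prkcd (1.23, 0.0438) rose. Without any 1 of the BaP or MAR1HI libraries 0 members were called, against 7 without either MAR1INT library. Cell cycle inhibitors passed as a list with 0 of 11 members called over all genes and 8 adjusted over the list alone (list adjusted p = 0.000222, and adjusted p = 0.524 with an estimated correlation). Btg2, an antiproliferative gene, stood at 6.85 ± 1.245 and 17.3 ± 5.42 TPM and Cdkn2d at 42.1 ± 8.16 and 83.8 ± 16.9. Without either MAR1INT library 5 of them rose.

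Ribosome biogenesis passed downward with 0 of 24 members called and 1 adjusted over the list alone (list adjusted p = 5.72e-09, and adjusted p = 0.509 with an estimated correlation). Mybbp1a stood at 75.3 ± 10.1 and 32.6 ± 2.08 TPM and the methyltransferase Fbl at 158 ± 60.7 and 73.5 ± 1.12. CD34 protein parted these gates, so a fall of Cd34 is not independent of the sort, and no list was tested without it. Progenitor genes passed downward (2 of 17 fell, Kit and Cd34, 3 adjusted over the list alone, list adjusted p = 1.64e-05, and adjusted p = 0.508 with an estimated correlation). Without either BaP library 1 of them fell, without either MAR1HI library 0 and without either MAR1INT library 4. S phase genes passed downward at a small size (median -0.15, 0 of 30 called, 0 adjusted over the list alone, list adjusted p = 0.00981, and adjusted p = 0.561 with an estimated correlation). Cdc6 stood at 33.2 ± 2.69 and 20.7 ± 0.837 TPM and Mcm2 at 51.1 ± 2.81 and 34.3 ± 7.78. G2 and mitosis genes did not pass (0 up and 0 down of 31, 0 and 0 adjusted over the list alone, adjusted p = 0.0787), but passed upward with no filter on low values (0.00118). Cenpf stood at 30.7 ± 0.858 and 62.1 ± 20.4 TPM and Kif23 at 52.1 ± 5.41 and 90.9 ± 21.4. Heat shock and dissociation genes passed downward (0 of 9 called, 1 adjusted over the list alone, list adjusted p = 0.0126, and adjusted p = 0.561 with an estimated correlation). Their call was lost without BaP replicate 2 (adjusted p = 0.153) and without MAR1HI replicate 1 (0.0914). Mast cell genes passed downward with Kit the only member called (1 of 5, 1 adjusted over the list alone, list adjusted p = 0.0285, and adjusted p = 0.508 with an estimated correlation). Kit was not called without either MAR1HI library. The list call was lost without MAR1HI replicate 2 (0.0791), with pseudocount 0.1 (0.0603) and after quantile normalization (0.118). The S phase and heat shock calls were lost with no filter on low values (0.176 and 0.0832). Without MAR1HI replicate 1 the heat shock median turned from -0.41 to 0.01.

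Several lists of markers of other marrow cells passed downward between MAR1HI and BaP, some with 0 called members. Of eosinophil markers 4 of 8 fell and 1 (Ccr3) rose (adjusted over the list alone, 6 and 2, list adjusted p = 2.90e-06, and adjusted p = 0.508 with an estimated correlation). Prg2, the major basic protein of eosinophils, stood at 1259 ± 459 and 56.2 ± 13.4 TPM without a call (adjusted p = 0.0747). The eosinophil list lost its call without genes listed at 0 in a whole group, a setting chosen after seeing the data (0.0643). Monocyte and macrophage markers fell in 5 of 15 members (10 adjusted over the list alone, list adjusted p = 1.90e-14, and adjusted p = 0.288 with an estimated correlation). Csf1r, a receptor of macrophage growth factors, fell from 34.5 ± 6.99 to 3.95 ± 0.357 TPM and Spic from 6.95 ± 0.555 to 0.215 ± 0.159. Dendritic cell markers fell in 4 of 11 (6 adjusted over the list alone, list adjusted p = 4.83e-09, and adjusted p = 0.438 with an estimated correlation), all MHC class II genes or Cd74. Neutrophil markers fell in 2 of 18 (3 adjusted over the list alone, list adjusted p = 3.304e-10, and adjusted p = 0.509 with an estimated correlation). Their list median stood at 174 and 563 TPM in the BaP libraries and at 183 and 151 in MAR1HI, and the median log2 change turned from -0.77 to 0.06 without BaP replicate 2. The granule protease Prtn3 fell from 53.2 ± 0.642 to 10.98 ± 1.99 TPM and myeloperoxidase Mpo from 1906 ± 328 to 555 ± 84.9. Erythroid markers (0 of 13 called, 0 adjusted over the list alone, list adjusted p = 0.000769, and adjusted p = 0.509 with an estimated correlation) passed downward. This call was lost without BaP replicate 2 (0.0885) and without MAR1HI replicate 2 (0.0810). T and NK cell markers (0 of 5 called, 2 adjusted over the list alone, list adjusted p = 0.00199, and adjusted p = 0.456 with an estimated correlation) passed downward, and Nkg7 stood at 376 ± 6.28 and 194 ± 0.084 TPM. Their list lost its call with no filter on low values (0.384) and after quantile normalization (0.0533). Without BaP replicate 1, BaP replicate 2, either MAR1HI library and either MAR1INT library, the eosinophil markers that fell numbered 2, 2, 0 and 6, the monocyte markers 1, 1, 0 and 11, the dendritic cell markers 2, 4, 0 and 6, and the neutrophil markers 5, 1, 0 and 8.

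JAK-STAT5 response genes did not pass between MAR1HI and BaP (2 up and 0 down of 13, 4 and 0 adjusted over the list alone, adjusted p = 0.0544), although Osm and Id1 rose. The list passed upward without BaP replicate 2 (adjusted p = 0.0315), without MAR1HI replicate 2 (0.0342) and under each of the 3 other scalings (0.0366 to 0.0393). Immediate early genes did not pass (1 up and 0 down of 17, 4 and 1 adjusted over the list alone, adjusted p = 0.323). Zfp36 rose, and the list passed upward with a mean TPM of 5 or more (0.00336, median 0.87). Its median was 0.71 as reported and 1.12 without BaP replicate 2. In glycolysis (2 up and 0 down of 19, 5 and 0 adjusted over the list alone, adjusted p = 0.411) Slc2a3 and Pfkp rose. In eicosanoid synthesis (1 up and 1 down of 11, 2 and 1 adjusted over the list alone, adjusted p = 0.205) Tbxas1 fell and Alox15 rose. In granule and exocytosis machinery (1 up and 0 down of 19, 3 and 0 adjusted over the list alone, adjusted p = 0.4) Lyst rose. That list passed upward with no filter on low values (0.0457). Lineage transcription factors (1 up and 0 down of 27, 1 and 0 adjusted over the list alone, adjusted p = 0.953) held 1 called member. Nfil3, a regulator of lymphoid and myeloid cells, rose from 18.0 ± 0.452 to 88.7 ± 31.1 TPM. Interferon-stimulated genes did not pass (0 up and 0 down of 19, 0 and 0 adjusted over the list alone, adjusted p = 0.277). Oxidative phosphorylation did not pass (0 up and 0 down of 20, 0 and 0 adjusted over the list alone, adjusted p = 0.601), and its test pointed down while its median and mean were above 0 in TPM. The median was -0.10 with FPKM, -0.10 after quantile normalization and -0.18 with median-of-ratios scaling. Apoptosis regulators (0 up and 0 down of 16, 0 and 0 adjusted over the list alone, adjusted p = 0.606) and B and plasma cell markers (0 up and 0 down of 6, 0 and 0 adjusted over the list alone, adjusted p = 0.523) did not pass. Of megakaryocyte and platelet markers (1 up and 0 down of 6, 2 and 1 adjusted over the list alone, adjusted p = 0.353) the integrin Itgb3 rose. Without BaP replicates 1 and 2, members that rose numbered 0 and 1 in each of the JAK-STAT5, immediate early, glycolysis and megakaryocyte lists, and members that fell in eicosanoid synthesis 0 and 1. Without either MAR1HI library 0 members of the lists in this paragraph were called, and without either MAR1INT library 5 glycolysis genes rose and 1 fell, and 3 transcription factors rose and 3 fell.

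Fewer genes were called between MAR1HI and BaP without any 1 of their 4 libraries, which also alters the pooled spread. Without BaP replicate 1, 67 genes rose and 20 fell, without BaP replicate 2 the counts were 87 and 26. Without MAR1HI replicate 1 they were 1 and 2, and without MAR1HI replicate 2 again 1 and 2. Of the 24 genes named for this contrast 16, 18, 3 and 3 were still called, the last 3 being Ccl6, H4bc24 and Scarna13. The MAR1INT libraries, which enter through the pooled spread, worked the other way. Without either of them, as with only the 2 groups compared (718 rose and 344 fell), more genes were called and all 282 calls remained. Only 3 genes rose and 1 fell with no filter on low values, 76 and 13 with pseudocount 0.1, and 135 and 90 with median-of-ratios scaling. The counts were 194 and 135 with FPKM, 235 and 178 after quantile normalization, and 320 rose with robust eBayes. Gpr174, H4bc24, Ear1 and H2-Eb1 lost their calls with median-of-ratios scaling. With fry, 12 list calls of this contrast were lost. These were adhesion (adjusted p = 0.0547), Fc epsilon receptor signalling (0.116), cell cycle inhibitors (0.0664), ribosome biogenesis (0.109), progenitor genes (0.0623) and S phase (0.428). The others were heat shock (0.464), mast cell (0.0511), eosinophil (0.0664), neutrophil (0.257), T and NK cell (0.0694) and erythroid genes (0.359), while the megakaryocyte list passed upward (0.0401).

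The second comparison set MAR1INT against MAR1HI, the populations that differ in the gate only by the level of MAR1 binding. Genes of DNA replication and mitosis were far lower in MAR1INT, with nearly every tested member of both cell cycle lists called. The granule proteases Mcpt8, Cpa3 and Gzmb and 6 of 17 progenitor genes fell too, although neither of their lists passed and both lists depended on the scaling. Of cytokines and chemokines 3 of 12 rose and 2 fell, and of surface receptors 6 of 27 rose and 3 fell. These lists and that of adhesion and migration lost their calls with fry (adjusted p = 0.134, 0.358 and 0.347) and with an estimated correlation. The mitotic regulator Birc5 (survivin) fell from 115 ± 10.6 to 1.29 ± 1.82 TPM (-5.94, adjusted p = 0.000218) and the phosphatase Cdkn3 from 158 ± 11.1 to 6.83 ± 9.66 (-5.38, 0.00539). The kinesin Kif22 fell from 75.1 ± 11.9 to 1.22 ± 0.186 (-5.09, 8.36e-05) and Shcbp1 from 49.0 ± 11.1 to 0.703 ± 0.994 (-4.99, 0.000328). The other 8 of the 12 largest falls were listed at 0 in both MAR1INT libraries. In MAR1HI replicates 1 and 2 these stood at 26.4 and 34.9 TPM for Cep55, a protein of the last step of cell division. They stood at 154 and 134 for Slirp, at 44.7 and 46.1 for Cox6b2, at 56.2 and 28.7 for Wfdc21 and at 27.8 and 37.4 for Stfa2l1. For Evi2 (124 and 164), H2-Q6 (89.8 and 125) and H2-Q9 (85.3 and 41.8), which overlap other genes of the same loci, the level of the single gene is uncertain.

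Of the 12 largest rises, Cd7 rose from 84.0 ± 29.4 to 544 ± 36.2 TPM (2.72, adjusted p = 0.00173) and Slc6a4 from 19.8 ± 1.61 to 116 ± 6.42 (2.49, 0.007). Wdr95 rose from 2.66 ± 1.29 to 75.7 ± 28.2 (4.39, 0.000607). The DNA repair glycosylase Tdg rose from 7.37 ± 2.25 to 49.5 ± 13.4 TPM and Unc93a from 2.29 ± 0.878 to 23.6 ± 2.77. The glutathione transferase Gstm3 rose from 1.54 ± 0.715 to 12.97 ± 1.86 TPM, the odorant receptor gene Olfr1033 from 3.25 ± 3.86 to 20.7 ± 8.74 and the noncoding RNA Lncpint from 0.0723 ± 0.102 to 6.93 ± 2.17. Socs2, a feedback inhibitor of cytokine signalling, rose from 0.482 ± 0.682 to 9.37 ± 9.72 TPM (2.47, adjusted p = 0.0402), at 16.2 and 2.495 TPM in replicates 1 and 2 of MAR1INT. It lost its call with FPKM and with median-of-ratios scaling. The histone genes H3c14 (8.59) and H4bc24 (7.93) and the class I gene H2-Q8 (2.79) have near-identical or overlapping copies, and their separate levels are uncertain.

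All 31 of 31 tested G2 and mitosis genes fell (31 adjusted over the list alone, list adjusted p = 9.85e-26, and adjusted p = 0.438 with an estimated correlation), with a median of -3.04. The cyclin Ccnb1 fell from 143 ± 34.7 to 5.60 ± 2.12 TPM and Dlgap5 from 70.0 ± 24.1 to 2.29 ± 1.26. So did the kinetochore gene Ndc80, from 81.3 ± 23.3 to 3.04 ± 0.0372. S phase genes fell in 27 of 30 members and rose in 0 (28 and 0 adjusted over the list alone, list adjusted p = 4.45e-16, and adjusted p = 0.438 with an estimated correlation), with a median of -2.69. The cyclin Ccne2 fell from 56.6 ± 4.10 to 1.70 ± 2.40 TPM. The ribonucleotide reductase subunit Rrm2 fell from 214 ± 0.83 to 22.2 ± 20.2. Without MAR1HI replicate 1 and without MAR1HI replicate 2 the S phase genes that fell numbered 18 and 12, and the mitosis genes 28 and 22. Cell cycle inhibitors went both ways (3 of 11 rose and 2 fell, the same counts adjusted over the list alone). The antiproliferative genes Btg1 (1.26) and Cdkn1b (0.94) rose and Cdkn2c fell (-2.53). Cdkn1a, at 4.66 and 5.03 TPM in MAR1HI, was listed at 0 in MAR1INT. That list passed upward (list adjusted p = 0.04, and adjusted p = 0.624 with an estimated correlation) with a median of 0.32 and a mean of -0.11. Without MAR1HI replicates 1 and 2, 0 and 1 of them rose and 1 and 0 fell. Its call was lost with fry (0.994), after quantile normalization (0.173), without BaP replicate 1 (0.0588), BaP replicate 2 (0.0614), MAR1INT replicate 1 (0.409) and MAR1INT replicate 2 (0.135).

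Oxidative phosphorylation fell in 7 of 20 members (10 adjusted over the list alone, list adjusted p = 0.00171, and adjusted p = 0.524 with an estimated correlation). Ndufa4 fell from 577 ± 28.2 to 229.6 ± 28.8 TPM and Cycs (cytochrome c) from 74.1 ± 0.323 to 28.3 ± 2.72. The call was lost without MAR1INT replicate 1 (0.159) and without MAR1INT replicate 2 (0.0725), and 2 and 0 members fell without MAR1HI replicates 1 and 2. Ribosome biogenesis fell in 5 of 24 (6 adjusted over the list alone, list adjusted p = 0.0454, and adjusted p = 0.674 with an estimated correlation). Utp20 fell from 6.76 ± 0.94 to 0.98 ± 0.492 TPM. That call was lost without BaP replicate 1 (0.0766), BaP replicate 2 (0.0741), MAR1HI replicate 1 (0.112), MAR1INT replicate 1 (0.158) and MAR1INT replicate 2 (0.440), and with median-of-ratios scaling (0.0658) and with array weights (0.0581). Its called members numbered 3 without either BaP library, 0 without either MAR1HI library and 8 without MAR1INT replicate 1.

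Cytokines and chemokines rose in 3 and fell in 2 of 12 members (adjusted over the list alone, 7 and 2, list adjusted p = 0.000155, and adjusted p = 0.511 with an estimated correlation). Ccl6 rose from 363 ± 18.1 to 1810.4 ± 105 TPM and Ccl9 from 269 ± 18.3 to 843 ± 77.6. Tnf fell (-2.14) and Il1b, at 1.41 and 2.39 TPM in MAR1HI, was listed at 0. In adhesion and migration 5 of 21 rose and 1 fell (adjusted over the list alone, 5 and 1, list adjusted p = 8.64e-05, and adjusted p = 0.618 with an estimated correlation). Ccr3 reached 126 ± 7.72 TPM, Cxcr2 472 ± 43.9 and Ccr2 592 ± 37.3, and Cxcr4, the receptor that retains cells in marrow, fell from 474 ± 120.2 to 139 ± 5.44. Basophil surface receptors rose in 6 and fell in 3 of 27 (adjusted over the list alone, 8 and 3, list adjusted p = 0.000687, and adjusted p = 0.509 with an estimated correlation). Csf2rb2, a beta chain of the interleukin 3 receptor, rose from 276 ± 12.9 to 734 ± 24.2 TPM. Clec12a fell from 308 ± 12.6 to 66.1 ± 26.9, beside Fcer1a and Cd24a (-1.34). The receptor call was lost after quantile normalization (0.209). Immediate early genes rose in 3 of 17 (Klf2, Junb and Zfp36, 3 adjusted over the list alone, list adjusted p = 0.000109, and adjusted p = 0.613 with an estimated correlation). Lineage transcription factors rose in 3 and fell in 1 of 27 (adjusted over the list alone, 4 and 1, list adjusted p = 0.000369, and adjusted p = 0.554 with an estimated correlation). Myc rose from 26.5 ± 2.07 to 69.2 ± 15.2 TPM and Runx2 from 16.7 ± 4.36 to 40.3 ± 3.15, and Myb fell from 73.5 ± 23.1 to 13.5 ± 6.04.

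JAK-STAT5 response genes rose in 3 of 13 (Socs2, Osm and Pim1) and fell in 0 (adjusted over the list alone, 3 and 1, list adjusted p = 0.00079, and adjusted p = 0.511 with an estimated correlation). The call was lost without MAR1INT replicate 2 (0.0888). Fc epsilon receptor signalling passed upward with Plcg1 higher and Fcer1a lower (1 and 1 of 25, adjusted over the list alone 0 and 1, list adjusted p = 0.00234, and adjusted p = 0.652 with an estimated correlation). No member rose with any 1 of the 6 libraries left out. It lost its call without MAR1INT replicate 1 (0.0681). Without MAR1HI replicate 1 and without MAR1HI replicate 2, members that rose numbered 2 and 2 for cytokines and chemokines, 2 and 3 for adhesion, and 1 and 1 for surface receptors. Of cytokines and chemokines 0 and 0 fell, and of surface receptors 2 and 0. Members that rose numbered 0 and 0 for immediate early genes, 0 and 0 for transcription factors, and 0 and 1 for JAK-STAT5 response. Without either BaP library 1 transcription factor rose, and without MAR1INT replicates 1 and 2 the JAK-STAT5 genes that rose numbered 2 and 1. Eosinophil markers passed upward with rises of Ccr3 and Siglecf, a pair of receptors that basophils also use (2 of 8, 2 adjusted over the list alone, list adjusted p = 0.0333, and adjusted p = 0.618 with an estimated correlation). This call rested on single libraries and on the scaling. It was lost without MAR1HI replicate 2 (0.0930) and without MAR1INT replicate 2 (0.618, with the list median turning from 0.07 to -0.47). It was also lost with median-of-ratios scaling (0.183), after quantile normalization (0.117), with pseudocount 0.1 (0.1102) and with no filter (0.0548). Only 1 member rose without either MAR1HI library and 4 without MAR1INT replicate 1.

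Basophil granule and effector genes did not pass as a list (1 up and 3 down of 17, 6 and 5 adjusted over the list alone, adjusted p = 0.243). The proteases Mcpt8 and Cpa3, among the most abundant transcripts of these cells, fell from 5627 ± 1115 to 2453 ± 413 TPM (-1.19, adjusted p = 0.00672) and from 2889 ± 182 to 1214 ± 330.3 (-1.28, 0.00449). The granzyme Gzmb fell from 9.79 ± 2.71 to 0.956 ± 0.177. Of the list 5 rose and 1 fell with median-of-ratios scaling, where Mcpt8 and Cpa3 lost their calls, and 4 rose and 3 fell after quantile normalization, with a median of -0.27 in TPM, 0.03 and 0.01. Without either MAR1HI library 0 of them fell, without MAR1INT replicate 1 5 did, and without MAR1HI replicate 1 the list passed upward (adjusted p = 0.0451). Progenitor genes (1 up and 6 down of 17, 1 and 6 adjusted over the list alone, adjusted p = 0.349) held falls of Cd34, Angpt1 (-2.45), Myb and Egfl7 (-2.19). Of these genes 3 and 1 fell without MAR1HI replicates 1 and 2, and after quantile normalization 3 fell and the median turned to 0.11. Glycolysis (1 up and 3 down of 19, 1 and 3 adjusted over the list alone, adjusted p = 0.308) held a rise of Aldoa (0.82) and falls of Pgk1 (-0.97), Tpi1 (-0.88) and Gapdh (-0.87). With median-of-ratios scaling 1 glycolysis gene rose and 0 fell, with a median of 0.25. Heat shock and dissociation genes (0 up and 3 down of 9, 0 and 4 adjusted over the list alone, adjusted p = 0.39) held falls of Hsp90aa1 (-1.45), Hsp90ab1 (-1.01) and Hspd1 (-1.17). Mast cell genes did not pass (0 up and 2 down of 5, 0 and 2 adjusted over the list alone, adjusted p = 0.353). In eicosanoid synthesis (1 up and 1 down of 11, 1 and 2 adjusted over the list alone, adjusted p = 0.818) Ptgr1 fell. Apoptosis regulators did not pass (0 up and 1 down of 16, 0 and 1 adjusted over the list alone, adjusted p = 0.352), and Fas, at 11.3 and 11.1 TPM in MAR1HI, was listed at 0 in MAR1INT. In granule and exocytosis machinery (2 up and 1 down of 19, 2 and 1 adjusted over the list alone, adjusted p = 0.205) Lyst rose and Lamp1 fell. Of interferon-stimulated genes (0 up and 2 down of 19, 0 and 0 adjusted over the list alone, adjusted p = 0.0871) Oas1a and Bst2 fell, and the list passed upward without MAR1INT replicate 1 (0.0446). Of the interferon list 2 rose and 0 fell after quantile normalization (median 0.60) and 2 rose and 1 fell with median-of-ratios scaling (0.27). Of apoptosis regulators 2 rose and 1 fell under both of these scalings (0.27 and 0.13), and of exocytosis genes 1 rose and 1 fell (0.07) and 4 rose and 1 fell (0.04). Many of these calls were lost without either MAR1HI library. This lowers the power and alters the pooled spread, so it does not show that 1 library carried them. Leaving out either MAR1HI library left 0 called members in the glycolysis, mast cell, eicosanoid, apoptosis and interferon lists, and leaving out either BaP library left 0 in the interferon list. Of heat shock genes 3 and 0 fell without MAR1HI replicates 1 and 2, and of exocytosis genes 0 and 1 rose and 1 and 0 fell.

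Among markers of other cells, no list but that of eosinophils passed between MAR1INT and MAR1HI. Of neutrophil markers (0 up and 4 down of 18, 0 and 4 adjusted over the list alone, adjusted p = 0.642) the protease Ctsg fell from 931 ± 8.23 to 101 ± 6.24 TPM. Without either MAR1HI library 2 of them fell, and without MAR1INT replicate 1 7 did. Of monocyte and macrophage markers (1 up and 0 down of 15, 1 and 0 adjusted over the list alone, adjusted p = 0.435) Adgre1 rose. Of dendritic cell markers (0 up and 3 down of 11, 0 and 3 adjusted over the list alone, adjusted p = 0.343) Itgax, H2-Aa and H2-Ab1 fell. Of T and NK cell markers (0 up and 2 down of 5, 0 and 2 adjusted over the list alone, adjusted p = 0.343) Nkg7 and Lck fell. B and plasma cell markers (0 up and 1 down of 6, 0 and 1 adjusted over the list alone, adjusted p = 0.396) held a fall of Vpreb3. Megakaryocyte and platelet markers (1 up and 1 down of 6, 1 and 2 adjusted over the list alone, adjusted p = 0.748) held a rise of Itgb3 and a fall of Gp1ba. Leaving out either MAR1HI library left 0 called markers of monocytes, dendritic cells, B and plasma cells, megakaryocytes and erythroid cells, and 1 of T and NK cells. Without MAR1INT replicates 1 and 2 the dendritic cell markers that fell numbered 4 and 5. After quantile normalization the medians of the T and NK cell, monocyte and erythroid lists turned to 0.06, 0.39 and 0.79. Erythroid markers did not pass (0 up and 1 down of 13, 0 and 0 adjusted over the list alone, adjusted p = 0.247), and they passed upward without MAR1HI replicate 1 (0.0188) and without MAR1INT replicate 2 (0.00260). The test pointed up while median and mean lay below 0 for the granule and effector, glycolysis, interferon, exocytosis, apoptosis, monocyte, erythroid and megakaryocyte lists, in a contrast whose median gene changed by -0.36.

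With fry, 10 list calls of this contrast were lost. Besides cytokines and chemokines, surface receptors and adhesion, given above, these were cell cycle inhibitors (adjusted p = 0.994), ribosome biogenesis (0.0664), transcription factors (0.418), immediate early genes (0.398), Fc epsilon receptor signalling (0.704), JAK-STAT5 response (0.156) and eosinophil markers (0.467). The mast cell (0.0328) and T and NK cell lists (0.0342) passed downward with fry. Fewer genes were called between MAR1INT and MAR1HI without either MAR1HI library, and more without either MAR1INT library. Between duplicates at 5 to 20 TPM the SD was 0.337 in MAR1HI and 0.8 in MAR1INT. These repeats alter the pooled spread, so they do not show which libraries carried the calls. Only 51 genes rose and 511 fell with no filter on low values, 130 and 1058 with array weights. The counts were 786 and 948 after quantile normalization and 806 and 1224 with median-of-ratios scaling. In simulations 10% of the calls of this contrast were false. Only 159 rose with only the 2 groups compared.

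The third comparison set MAR1INT against BaP, the populations farthest apart. Some members of the cytokine and chemokine (8 of 12), adhesion and migration (16 of 21), Fc epsilon receptor signalling (11 of 25), immediate early (7 of 17) and cell cycle inhibitor (6 of 11) lists rose, while a few others fell. Each of these lists too lost its call with an estimated correlation. The alpha chain of the IgE receptor itself, Fcer1a, fell (-0.81, adjusted p = 0.0141). Cd7 rose from 2.69 ± 1.77 to 544 ± 36.2 TPM (7.29, adjusted p = 1.13e-05) and Slc6a4 from 1.63 ± 1.68 to 116 ± 6.42 (5.64, 7.88e-05). Ccl6 rose from 48.9 ± 0.772 to 1810.4 ± 105 TPM (5.18, 1.21e-06) and Il7r from 3.55 ± 2.21 to 103 ± 9.78 (4.61, 0.000102). Defb40, listed at 0 in BaP, stood at 135 and 81.0 TPM in the MAR1INT libraries. The kinase Mapk12 rose from 0.279 ± 0.395 to 31.5 ± 8.15 TPM and the metalloprotease Adam8 from 10.3 ± 5.34 to 241 ± 28.0. C3ar1 rose from 7.18 ± 1.35 to 181 ± 18.1, the nuclease Dnase2b from 0.469 ± 0.274 to 29.7 ± 2.13 and Wdr95 from 0.294 ± 0.416 to 75.7 ± 28.2. Evi2b (4.92) and H3c14 (6.52), uncertain for the reasons given, were the others of the 12. Among the largest falls were Cd34 (-5.53, adjusted p = 6.91e-05), Birc5 (-5.71, 0.000124) and H2-Aa (-6.25, 0.000101). Prg2 fell from 1259 ± 459 to 36.0 ± 48.2 TPM (-6.39, 0.00253), and its call was lost with no filter on low values and with robust eBayes. Epx and Prg3 were listed at 0 in MAR1INT after 64.9 and 33.3 and 96.2 and 33.3 TPM in BaP, and Slirp, H2-Q6, H2-Q9, Wfdc21, Cox6b2 and Scarna13 were also listed at 0.

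Adhesion and migration genes rose in 16 and fell in 2 of 21 members (adjusted over the list alone, 17 and 2, list adjusted p = 3.17e-08, and adjusted p = 0.524 with an estimated correlation). The same list held Ccr3, from 5.46 ± 0.215 to 126 ± 7.72 TPM, Cxcr2, from 47.5 ± 12.3 to 472 ± 43.9, and Ccr2, from 70.7 ± 20.5 to 592 ± 37.3. Basophil surface receptors rose in 14 and fell in 3 of 27 (adjusted over the list alone, 14 and 4, list adjusted p = 1.04e-06, and adjusted p = 0.504 with an estimated correlation). Il18r1 stood at 518 ± 26.6 and Hrh4 at 365 ± 29.6 TPM in MAR1INT. In cytokines and chemokines 8 of 12 rose and 2 fell (adjusted over the list alone, 8 and 3, list adjusted p = 5.44e-05, and adjusted p = 0.509 with an estimated correlation). Ccl9 rose from 77.0 ± 16.6 to 843 ± 77.6 TPM, Ccl4 to 541 ± 62.2 and Ccl3 to 1598 ± 75.7. Fc epsilon receptor signalling rose in 11 and fell in 2 of 25 (adjusted over the list alone, 13 and 2, list adjusted p = 1.64e-05, and adjusted p = 0.618 with an estimated correlation). The adaptor Gab2 rose (1.83), and 5 members rose without BaP replicate 1. Granule and effector genes rose in 9 and fell in 5 of 17 (adjusted over the list alone, 9 and 5, list adjusted p = 0.0254, and adjusted p = 0.524 with an estimated correlation). Csf1 rose (1.80) and Ptgs1 fell (-2.15). As a list they lost the call without MAR1HI replicate 2 (0.0532) and after quantile normalization (0.183). Only 3 members fell without BaP replicate 2 and without either MAR1HI library.

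Immediate early genes rose in 7 and fell in 1 of 17 (adjusted over the list alone, 8 and 1, list adjusted p = 0.00166, and adjusted p = 0.624 with an estimated correlation). Zfp36 rose from 20.97 ± 12.3 to 218 ± 11.7 TPM and Junb from 8.63 ± 3.14 to 63.2 ± 2.06. JAK-STAT5 response genes rose in 6 and fell in 1 of 13 (adjusted over the list alone, 8 and 1, list adjusted p = 0.00127, and adjusted p = 0.524 with an estimated correlation). Osm (2.96) and Pim2 (2.38) rose and Bcl2 fell (-1.99). Without BaP replicate 1 and without either MAR1HI library 4 of these rose. Cell cycle inhibitors rose in 6 and fell in 1 of 11 (adjusted over the list alone, 6 and 2, list adjusted p = 0.00199, and adjusted p = 0.56 with an estimated correlation). Btg1 rose from 31.6 ± 1.91 to 151 ± 1.64 TPM and Btg2 from 6.85 ± 1.245 to 27.0 ± 0.776, and 3 rose without BaP replicate 1. Lineage transcription factors rose in 9 and fell in 3 of 27 (adjusted over the list alone, 9 and 3, list adjusted p = 0.0141, and adjusted p = 0.624 with an estimated correlation). Runx2 (2.36) and Nfil3 (2.67) rose and Myb (-3.47) and Cebpe (-2.50) fell. This call was lost without MAR1INT replicate 1 (0.0922) and without MAR1INT replicate 2 (0.0675), and 5 fell without MAR1INT replicate 1.

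All 31 of 31 G2 and mitosis genes were lower in MAR1INT than in BaP (31 adjusted over the list alone, list adjusted p = 5.62e-17, and adjusted p = 0.504 with an estimated correlation). Ccnb1 stood at 113 ± 22.2 TPM in BaP and Dlgap5 at 48.4 ± 8.14. Cdc25c was listed at 0 in MAR1INT. S phase genes fell in 28 and rose in 0 of 30 (adjusted over the list alone, 28 and 1, list adjusted p = 5.21e-13, and adjusted p = 0.438 with an estimated correlation). Chaf1b fell from 35.6 ± 5.52 to 1.94 ± 2.74 TPM. Ribosome biogenesis fell in 15 of 24 (20 adjusted over the list alone, list adjusted p = 1.98e-05, and adjusted p = 0.524 with an estimated correlation). Rrp12 fell from 5.78 ± 1.20 to 0.37 ± 0.506 TPM and Dkc1, the pseudouridine synthase of ribosomal RNA, from 102 ± 35.9 to 23.9 ± 1.48. Its lower members numbered 5 without BaP replicate 1 and 10 without BaP replicate 2. Oxidative phosphorylation fell in 7 of 20 (7 adjusted over the list alone, list adjusted p = 0.00608, and adjusted p = 0.544 with an estimated correlation). Cycs fell from 121 ± 47.8 to 28.3 ± 2.72 TPM. The call was lost without MAR1INT replicate 1 (0.161) and without MAR1INT replicate 2 (0.0884), and 2 fell without BaP replicate 1. Progenitor genes fell in 8 and rose in 1 of 17 (adjusted over the list alone, 8 and 1, list adjusted p = 0.0141, and adjusted p = 0.524 with an estimated correlation). Myb, the endothelial and stem cell gene Egfl7 (-3.38) and Cd34, whose protein parted these gates, were among those that fell. The call was lost with a mean TPM of 5 or more (0.158).

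**Figure D3:**
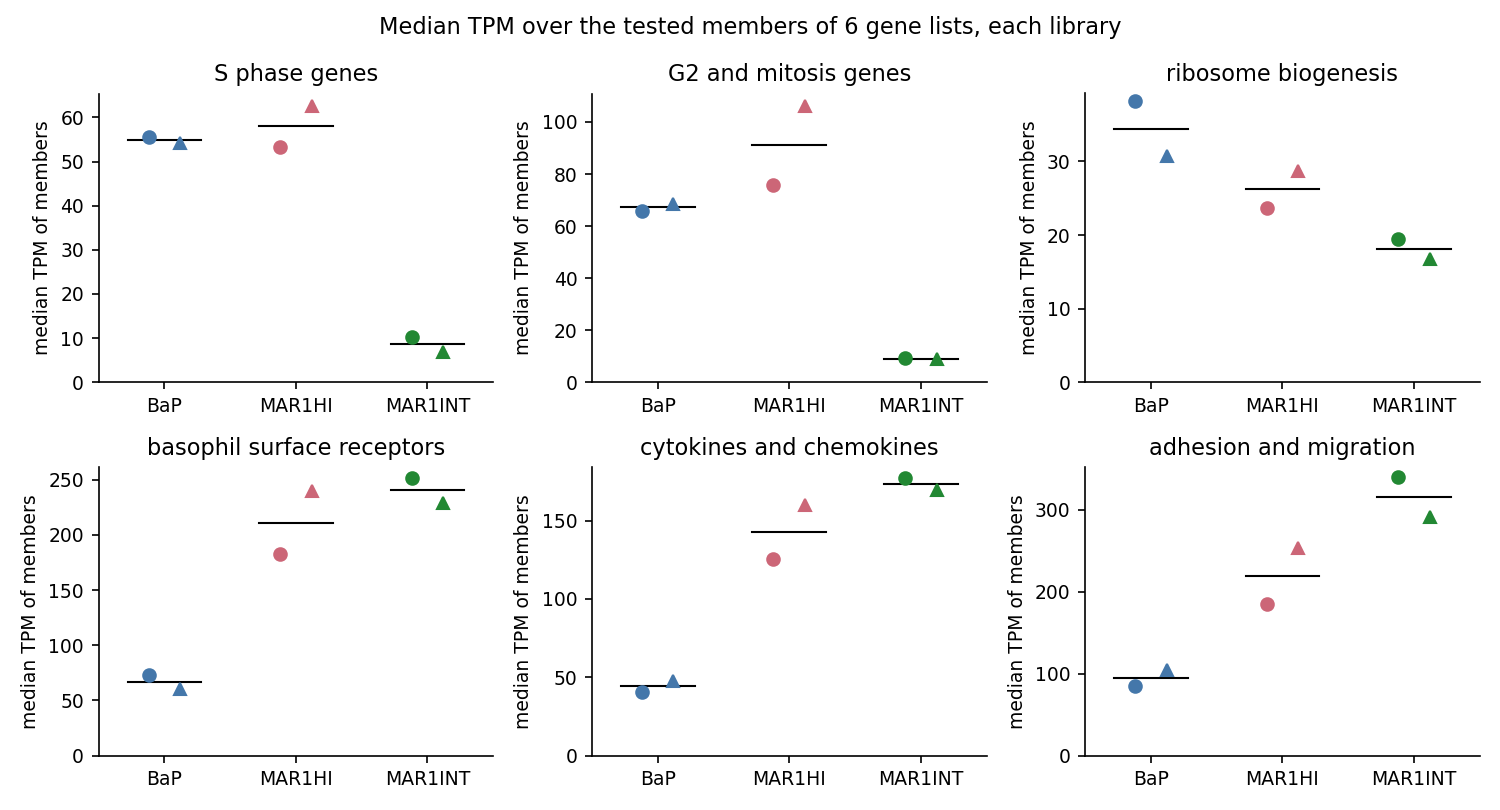
Median TPM of the tested members of 6 lists (S phase, G2 and mitosis, ribosome biogenesis, basophil surface receptors, cytokines and chemokines, adhesion and migration) in each library, with a line at the mean of each group. S phase and G2 and mitosis genes were low in both MAR1INT libraries only.

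Several lists of markers of other marrow cells passed downward between MAR1INT and BaP. Dendritic cell markers fell in 8 of 11 (8 adjusted over the list alone, list adjusted p = 0.00041, and adjusted p = 0.508 with an estimated correlation). H2-Ab1 fell from 166 ± 97.8 to 5.88 ± 2.01 TPM. Monocyte and macrophage markers fell in 10 of 15 (10 adjusted over the list alone, list adjusted p = 0.000769, and adjusted p = 0.438 with an estimated correlation). The complement gene C1qa (-3.87) and Csf1r (-2.95) fell. Neutrophil markers fell in 8 of 18 (9 adjusted over the list alone, list adjusted p = 0.00102, and adjusted p = 0.618 with an estimated correlation). Mpo fell from 1906 ± 328 to 89.0 ± 33.8 TPM. The list call was lost without BaP replicate 2 (0.0885), and 13 fell without BaP replicate 1. T and NK cell markers fell in 4 of 5 (4 adjusted over the list alone, list adjusted p = 0.0346, and adjusted p = 0.508 with an estimated correlation). Nkg7 fell from 376 ± 6.28 to 41.9 ± 13.5 TPM, and 2 fell without BaP replicate 2. That list lost its call without MAR1INT replicate 2 (0.0872), with FPKM (0.105), with median-of-ratios scaling (0.0605), after quantile normalization (0.183) and with no filter (0.190). The monocyte and the dendritic cell markers that fell numbered 5 and 5 without either BaP library. Eosinophil markers did not pass (2 up and 5 down of 8, 2 and 6 adjusted over the list alone, adjusted p = 0.148). This was so although Epx, Prg2, Prg3 and Ear1 (-5.45) fell, while Ccr3 and Siglecf rose. They passed downward without MAR1INT replicate 1 (0.00165) and without MAR1INT replicate 2 (2.15e-10), and 3 fell without either BaP library.

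The remaining lists did not pass between MAR1INT and BaP. Of heat shock and dissociation genes (0 up and 4 down of 9, 0 and 4 adjusted over the list alone, adjusted p = 0.0988) Hspe1 fell. Of mast cell genes (0 up and 2 down of 5, 0 and 2 adjusted over the list alone, adjusted p = 0.148) Kit and Cpa3 fell. In glycolysis (7 up and 4 down of 19, 8 and 4 adjusted over the list alone, adjusted p = 0.2) Hk3 and Aldoa rose and Pdk1 fell. In eicosanoid synthesis (2 up and 5 down of 11, 2 and 5 adjusted over the list alone, adjusted p = 0.39) Hpgd and Tbxas1 fell. In granule and exocytosis machinery (6 up and 3 down of 19, 7 and 3 adjusted over the list alone, adjusted p = 0.247) Lyst rose. Apoptosis regulators (3 up and 3 down of 16, 3 and 3 adjusted over the list alone, adjusted p = 0.382) held a rise of Bbc3 (1.82) and of Birc3 (1.51). Interferon-stimulated genes (4 up and 4 down of 19, 4 and 5 adjusted over the list alone, adjusted p = 0.513) held a rise of Zbp1 and falls of Oas1a, Ifit3 and Bst2. Of megakaryocyte and platelet markers (1 up and 2 down of 6, 3 and 2 adjusted over the list alone, adjusted p = 0.523) Itgb3 rose and Pf4 fell. Erythroid markers (0 up and 1 down of 13, 0 and 1 adjusted over the list alone, adjusted p = 0.355) and B and plasma cell markers (0 up and 0 down of 6, 0 and 0 adjusted over the list alone, adjusted p = 0.69) did not pass. Without BaP replicate 1 the heat shock list (0.00932) and the mast cell list (0.0415) passed downward. The median turned to -0.07 for interferon-stimulated genes with FPKM, and after quantile normalization to 0.28 for exocytosis, 0.35 for B and plasma cell and 0.29 for megakaryocyte genes. The test pointed up while the median lay below 0 for glycolysis, exocytosis and megakaryocyte genes, and while the mean lay below 0 for interferon and megakaryocyte genes. Members that rose without BaP replicate 1 and without BaP replicate 2 numbered 3 and 5 for glycolysis, 2 and 2 for exocytosis, 1 and 0 for interferon-stimulated genes, and 1 and 1 for apoptosis. Those that fell numbered 2 and 3 for glycolysis, 0 and 0 for exocytosis, 0 and 1 for interferon-stimulated genes, 1 and 0 for apoptosis, and 4 and 2 for eicosanoid synthesis. Without MAR1INT replicate 1 2 exocytosis genes rose. Over the contrast, 591 genes rose and 1248 fell without BaP replicate 1, and 698 and 1389 without BaP replicate 2. With no filter on low values 796 genes rose, and after quantile normalization 2302. With fry, 5 list calls of this contrast were lost: transcription factors (adjusted p = 0.133), cell cycle inhibitors (0.0664), immediate early genes (0.194), Fc epsilon receptor signalling (0.0817) and neutrophil markers (0.0817). The mast cell list passed downward with fry (0.0111). The granule and effector list median turned to -0.09 with no filter on low values.

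MAR1HI lay nearer to BaP than to MAR1INT over the genes that separated the latter pair. Over 3574 genes called between MAR1INT and BaP the median position of MAR1HI was 0.33 (0 at BaP, 1 at MAR1INT). It ranged from 0.31 to 0.35 over the 8 choices of 1 library per group (SD 0.0155), which reuse the same libraries and genes. With 1 library left out and genes called anew it ranged from 0.263 to 0.373. Of the genes 78.8% lay between the groups, 18.5% on the far side of BaP and 2.71% beyond MAR1INT. For the 1263 genes that rose the median was 0.61, and for the 2311 that fell it was 0.17. A pair of contrasts that share MAR1HI is not independent. Rises in both steps were shared by 62 genes (4.7 for independent lists), among them Cd7, Slc6a4, Ccl6 and Ccr3. Falls in both were shared by 18 genes (10.8 for independent lists), among them Cd34, Kit and Mpo. Simulations of no effect gave 0 shared genes, since hardly any gene was called in them, so they do not show what the shared libraries add, and no excess is read from these counts.

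Few genes were highest or lowest in MAR1HI. Of the 14 highest (29.9 for independent lists), Gpr174 stood at 3.09 ± 4.35 TPM in MAR1INT and Muc20 at 7.94 ± 2.08, 63.0 ± 13.8 and 15.8 ± 3.28 TPM across the groups. The gap junction gene Gja1 stood at 4.04 ± 0.933, 26.9 ± 11.8 and 7.39 ± 1.254 TPM and the integrin Itga8 at 6.21 ± 0.613, 25.4 ± 5.03 and 7.94 ± 1.23. The anion exchanger Slc26a3 stood at 22.9 ± 0.759, 79.6 ± 17.6 and 36.2 ± 2.23 TPM. Evi2 is uncertain as described. Of the 3 lowest (1.7 for independent lists), the macrophage surface gene Adgre1 stood at 33.2 ± 11.9, 6.94 ± 0.615 and 36.5 ± 15.6 TPM, and H4bc24 is 1 of many histone copies. Without BaP replicate 1, BaP replicate 2, either MAR1HI library, MAR1INT replicate 1 and MAR1INT replicate 2 the highest numbered 9, 7, 0, 79 and 85, and the lowest 4, 2, 1, 18 and 26.

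Markers of other cells were present in the sorted libraries at levels that differed between duplicates. The eosinophil and MHC class II genes called between MAR1HI and BaP were all higher in BaP replicate 1 than in replicate 2 (8 of 8). Of the 18 neutrophil markers 17 were higher in BaP replicate 2. Hba-a1 and Hba-a2, near-identical globin genes, exchanged levels between libraries, while their sum was 1471 and 1665 TPM in BaP, 1155 and 559.5 in MAR1HI and 1987 and 1215 in MAR1INT.

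**Figure D4:**
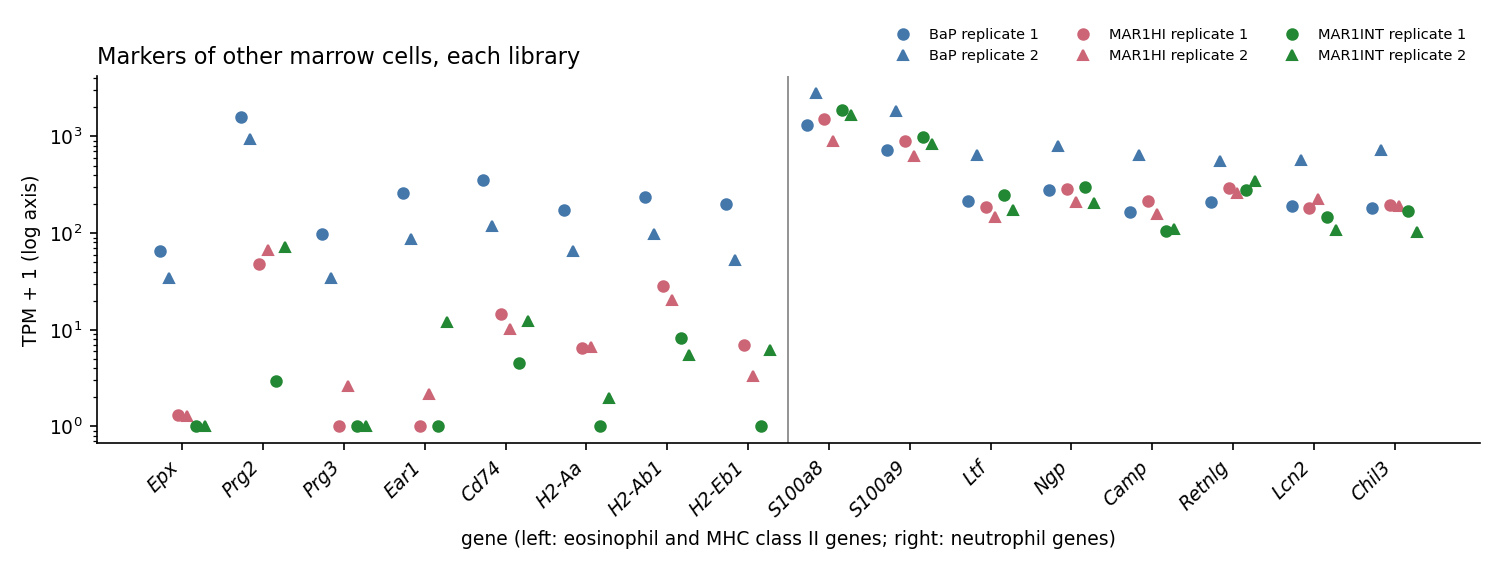
TPM + 1 (log axis) in each library of genes of eosinophils and antigen-presenting cells (left: Epx, Prg2, Prg3, Ear1, Cd74, H2-Aa, H2-Ab1, H2-Eb1) and of neutrophils (right: S100a8, S100a9, Ltf, Ngp, Camp, Retnlg, Lcn2, Chil3), chosen after the values were seen. The left genes were highest in BaP replicate 1.

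Some genes listed at 0 in a whole group overlap other genes. Of the tested genes 616 were at 0 in both MAR1INT libraries, against 25 in BaP and 27 in MAR1HI. At 20 TPM or more in both MAR1HI libraries and 0 in both MAR1INT libraries stood 22 genes, and the reverse held for 0 genes. Of the 22, 14 overlap another listed gene, of which 7 have no overlapping gene that gained TPM, and 8 do not, among them Cep55, Cox6b2, Gins1, Pole2, Haus1 and Cenpw, chosen after the values were seen. Scarna13, listed at 0 in MAR1HI, overlaps Mir3069, which stood at 0.216 and 0.215 TPM in BaP and at 125 and 85.1 in MAR1HI.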

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

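The number of called genes moved with several choices. Of the 215 repeated counts and positions 130 stayed within 1.5 times of the value reported (the position within its SD) and 85 moved, and of the 1614 repeated list tests 1462 stayed on the same side of the threshold, 123 became weaker, 28 became stronger and 1 reversed in the direction of the test. The sign of the list median, which is separate from that direction, turned in 54 of the 1614, 23 of them over the 3 other scalings. For lists that passed as reported it turned 7 times: for granule and effector genes in MAR1INT minus BaP with no filter (-0.09), for adhesion (-0.02) and Fc epsilon receptor signalling (-0.08) in MAR1INT minus MAR1HI and heat shock genes in MAR1HI minus BaP (0.01) without MAR1HI replicate 1, for neutrophil markers in MAR1HI minus BaP without BaP replicate 2 (0.06), and for eosinophil markers in MAR1INT minus MAR1HI with pseudocount 0.1 (-0.46) and without MAR1INT replicate 2 (-0.47). The repeat without genes at 0 in a whole group was chosen after seeing the data, and the cause of each shift was not tested. For MAR1HI minus BaP the 207 genes that rose became 76 with pseudocount 0.1, 3 with no filter on low values, 135 with median-of-ratios scaling, 320 with robust eBayes, 44 at an adjusted p under 0.01 and 718 with only the 2 groups compared, and ranged from 1 to 753 without 1 library. The 75 that fell became 13, 1 with no filter, 135 with FPKM, 178 after quantile normalization, 14 at the stricter p, 344 with only the 2 groups and 35 without genes at 0 in a whole group, and ranged from 2 to 335. For MAR1INT minus MAR1HI the 260 that rose became 51 with no filter, 786 after quantile normalization, 806 with median-of-ratios scaling, 130 with array weights, 170 at an absolute log2 change of 1 or more, 65 at the stricter p and 159 with only the 2 groups, and ranged from 48 to 351. The 1640 that fell became 511 with no filter, 948 after quantile normalization, 1058 with array weights and 696 at the stricter p, and ranged from 255 to 2245. For MAR1INT minus BaP the 1263 that rose became 796 with no filter, 2302 after quantile normalization and 612 at the stricter p (591 to 1416 without 1 library), and the 2311 that fell became 1216 at the stricter p (1248 to 2591). The 3012 genes that differed among the groups became 1449 with no filter and 1427 at the stricter p (1856 to 4053). The 14 genes highest in MAR1HI became 3 with pseudocount 0.1, 0 with no filter, 5 after quantile normalization, 8 with median-of-ratios scaling, 2 at the stricter p and 8 without genes at 0 in a whole group (0 to 85 without 1 library). The 3 lowest became 1 with pseudocount 0.1, 0 with no filter, 10 after quantile normalization and 0 at the stricter p (1 to 26). The median position of 0.33 became 0.288 with pseudocount 0.1, 0.384 with no filter, 0.387 after quantile normalization, 0.354 with median-of-ratios scaling, 0.311 at an absolute log2 change of 1 or more and 0.312 at the stricter p (0.263 to 0.373 without 1 library). Of the list tests, 48 passed as reported, 0 with an estimated correlation, 25 with fry and 42 to 47 without 1 library. The eosinophil list in MAR1INT minus MAR1HI reversed from a median of 0.07 to -0.47 without MAR1INT replicate 2, and ranged up to 0.95 without MAR1INT replicate 1.

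The replicate number was not shown by the labels to pair the libraries: deviations of same-numbered libraries from their group means correlated at 0.154, -0.0922 and -0.0592 across genes. With the replicate block 146 genes rose and 65 fell in MAR1HI minus BaP, 206 and 1554 in MAR1INT minus MAR1HI, and 1139 and 2255 in MAR1INT minus BaP. With that block 2827 genes differed among the groups, 12 were highest and 3 lowest in MAR1HI, the median position was 0.316 and 48 list tests passed. Under the block ribosome biogenesis lost its call in MAR1INT minus MAR1HI (adjusted p = 0.0663) and JAK-STAT5 response gained one in MAR1HI minus BaP (0.0487).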

Other observations

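All tests in this part were chosen after the results were seen. In BaP 8 eosinophil and MHC class II genes were called higher than in MAR1HI, although the gate was lineage-negative. If 1 mix of other marrow cells had been carried into both BaP libraries, its genes would have been expected to differ in the same direction between the duplicates. These 8 genes were higher in BaP replicate 1 (median log2 1.54) while the neutrophil list was higher in replicate 2 (-1.45). Each median lay beyond the SD of its members (0.337 and 0.645). That SD is over genes, so 1 pair of libraries cannot settle whether 1 mix was the source. A mix without neutrophils stays open too, since the neutrophil transcripts need not come from carried cells. Eosinophil-lineage cells inside the gate cannot be told apart from basophil precursors that use these genes, since Siglecf, Ccr3 and Il5ra, which basophils use themselves, differed by only 0.0680 between the duplicates (SD over all genes 0.598). Single-cell profiles of the same gate would separate these hypotheses.

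The 22 genes at 0 in both MAR1INT libraries despite 20 TPM or more in both MAR1HI libraries raise the question of read assignment. Where another gene overlapped, in 5 of 14 the summed TPM changed by under 1 (log2) while an overlapping gene gained at least 25% of the lost TPM, and in 7 no overlapping gene gained. Of the 5, Snord58b and Snord68 lie in hosts that gained 1894 and 685.3 TPM and cannot test it, so with few genes left reads given to an overlapping gene cannot be told apart from a real fall for this set. A further 8 genes had no overlapping gene listed at 1 TPM or more in either MAR1INT library, which argues against that explanation for them. Most of these 8 belong to the cell cycle or its replication machinery (Cenpw, Cep55, Gins1, Haus1, Pole2). Reads from the 14 genes would need to be assigned anew to settle them.

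MAR1INT had more genes at 0 and a wider spread between duplicates than the other groups. The aligned bases, 0.983 times those of BaP at 1.58 times its spread, argue against fewer bases as the source. At 5 to 20 TPM the spread was 1.64 times the larger of the other groups. Each SD rests on 1 pair of libraries, so fewer genes in use stays open. A smaller number of captured RNA molecules stays open, since at 50 to 200 TPM, where sampling matters less, the ratio was 0.980 against BaP but 1.53 against MAR1HI. Input cell numbers or RNA yields would be needed to test it.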
